A study of Mus musculus with 3 samples.

How the data were processed

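The deposited table held counts, which the values showed to be raw UMI counts (unique molecular identifiers, 1 per captured transcript) per gene and cell barcode, with no normalization. It covered 3 single-cell RNA libraries of mouse kidney, 2 of diabetic mice and 1 of a normal mouse. The labels did not state which diabetic sample each of the 2 diabetic libraries was, so these are named DM1 and DM2 after the prefixes of their cells, and the normal library is named NM. The authors named bcl2fastq, FastQC, Trimmomatic, cutadapt, Cell Ranger and STAR, without versions, and the mouse genome build mm10. They stated no cell filter, but no barcode had more than 2999 detected genes or 50% or more mitochondrial counts, and each library had its own lowest UMI total (2113 in DM1, 2727 in DM2 and 3932 in NM). The table had 15661 genes and 9272 barcodes, and 11 barcode sequences occurred in more than 1 library and were kept apart by library.

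Cells were required to have at least 200 detected genes and under 50% mitochondrial counts, which removed none. Scrublet, run per library through scanpy 1.11.5, marked 12 of 9272 cells (0.129%) as doublets. A yield under 0.5% in more than 5000 cells was taken as a failure of the caller, so no cell was removed. Counts were scaled to 10000 per cell and log transformed. Clusters came from 2000 highly variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15), with no correction between libraries, and gave 31 clusters. A cluster of at least 20 cells took the name of the class, among 22 classes with fixed marker lists, of which at least 3 markers were enriched 2-fold (after adding 20 CPM, counts scaled to the library total) and present in 10% of its cells. A cluster whose leading genes belonged to another cell type, or whose Malat1 (a nuclear long noncoding RNA) was under 10% of the level over all cells, stayed unnamed, a rule added after the clusters were seen. The class names rest on markers alone. Clusters 8, 14, 18 and 30 made up the proximal tubule class. Cluster 14 was called S1-like for its Slc5a2 and Slc5a12, and clusters 18 and 30 S3-like for their Kap and Slc7a13.

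Shares of cells carry exact Clopper-Pearson 95% intervals, and levels in CPM carry exact Poisson 95% intervals. A count of 0 was replaced by a floor of 3 counts per library when a fold was computed. Ratios against 1 to 3 counts are given with an exact 95% counting interval. These intervals and floors cover counting error only. In the tests of explanations, the intervals of list medians, of their differences and of the UMI ratio are bootstrap intervals, from resampling. For list medians the genes of the list were resampled. Genes are not independent replicates, so these intervals carry no error between mice. With 2 libraries against 1, no exact permutation test of a single value can reach a p below 0.333, so shares were not tested.

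Counts were summed per library and class, and diabetic was compared with normal in each class with at least 20 cells in every library (the proximal tubule, thick ascending limb and macrophage or monocyte classes) and over all cells. Injured tubule, proliferating and other classes below that number in a library were not tested. The fit was edgeR 4.0.16 quasi-likelihood in R 4.3.3, with TMM normalization and filterByExpr, at a Benjamini-Hochberg adjusted p under 0.05. It had 1 residual degree of freedom, from the 2 diabetic libraries, and the lone normal library was assumed to vary like them. The test was checked on simulated counts with 200 changed genes. At the dispersion of the proximal tubule class it made 63 calls, 0 of them false, and found 4.21% of 2-fold and 62.8% of 4-fold changes. At a lower dispersion (biological coefficient of variation 0.069 in place of 0.218) it made 150 calls, 12 of them false. It then found 52.6% of 2-fold and 91.7% of 4-fold changes. The absence of false calls therefore held only at the first dispersion. The simulation drew genes independently, with a common dispersion, and gave every library the same profile apart from the changed genes. It left out differences in make-up between libraries, so it does not give the rate of false calls in these data. Differences between classes in the diabetic change were tested by an edgeR interaction where each library had at least 50 cells of both classes.

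The 36 gene lists, the marker lists, the rule for named genes, the tests and the main alternatives were chosen before the data were examined. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists and classes. At the preset correlation camera compares genes with genes, so its p carries no error between mice. With an estimated correlation, and in fry, the error rests on 1 residual degree of freedom. A list could hardly pass there, so not passing does not decide on a list. List medians are medians of fitted log2 fold changes. Members of a list were also counted with p values adjusted over the list alone. Log2 ratios of single libraries used CPM plus 1. In the per-class comparison of DM1 with NM, genes had at least 30 counts, and each list median was ranked among those of 10000 random lists drawn from 10 bins of expression level.

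Named genes were, in the proximal tubule class, the 8 largest rises and 8 largest falls among called genes with at least a 1.5-fold difference in each diabetic library and a mean of at least 20 CPM, and 3 of each in the other tested classes. Places left empty went to genes with at least 30 counts, given as values. Mitochondrial, haemoglobin, ribosomal and immunoglobulin genes, Gm and Rik names and markers of other classes were left out of this part. Of each list the 2 highest and the 2 most changed members could be named, and a fixed set of genes of diabetic and tubular biology was always looked up, of which Ren1 had no row. Not every gene that the rule takes is named in the text. Genes named outside this rule, such as leading genes of clusters, members of small counts and further members of a list, were chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, the assembly of build mm10, in which 15155 of the 15661 gene names were found once and 482 were not found.

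Alternatives fixed in advance were DESeq2 size factors, no low-count filter, DESeq2 1.42.0, limma-voom, mitochondrial and haemoglobin genes left out, a limit of 25% mitochondrial counts, no such limit, Scrublet calls kept, Leiden resolutions 0.5 and 2, cells thinned to 2000 UMIs, a count minimum of 100, an estimated correlation and each diabetic library left out. Alternatives that changed the clusters in the proximal tubule class, and most of those applied to the lists, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.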

Results

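Single-cell RNA sequencing was carried out on kidneys of male C57BL/6J mice aged 4 weeks. Of the 3 animals, 2 had been made diabetic with streptozotocin, a toxin of insulin-producing beta cells, at 40 mg/kg on 5 consecutive days, with a fasting glucose of at least 16.7 mmol/L on day 7 after the last injection, and 1 was normal. Library DM1 held 4484 cells and 22176901 UMIs in total, DM2 held 2981 cells and 11406025 UMIs, and NM held 1807 cells and 12153668 UMIs. The median cell had 4045 UMIs in DM1, 3388 in DM2 and 5985 in NM. Mitochondrially encoded transcripts, which increase in damaged cells and are abundant in tubule cells, took a median of 11.3% of a cell's counts in DM1, 37.0% in DM2 and 14.9% in NM. The normal group had no replicate, so no value of NM carries an error between mice. Levels are in CPM of the counts summed over a class in a library.

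The first comparison asked which kinds of kidney cells differed in number between diabetic and normal mice. Injured tubule cells, marked by Havcr1 (kidney injury molecule 1), Vcam1 and Spp1 (osteopontin), made up 6.53% (5.83 to 7.30) of DM1 and 3.96% (3.29 to 4.72) of DM2 but 0.221% (0.0603 to 0.566) of NM. Havcr1 and Gdf15, a stress-induced cytokine, led this cluster and themselves differed between the groups, so its size was not independent of them. Proliferating cells made up 3.55% (3.02 to 4.13) of DM1, 4.13% (3.44 to 4.90) of DM2 and 0.830% (0.465 to 1.37) of NM. Cells of the thick ascending limb, which reabsorbs salt, were fewer in both diabetic libraries, at 2.92% (2.45 to 3.46) in DM1 and 0.705% (0.437 to 1.07) in DM2 against 6.25% (5.18 to 7.47) in NM. The distal convoluted tubule, principal cell, dendritic cell and fibroblast shares also lay below the normal one in both diabetic libraries.

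The diabetic libraries differed more from each other than from NM in several classes. Proximal tubule cells made up 9.81% (8.96 to 10.7) of DM1, 61.1% (59.3 to 62.8) of DM2 and 14.2% (12.6 to 15.9) of NM, and macrophages or monocytes 26.8%, 3.05% and 16.3%. In all, 7 classes had both diabetic intervals on the same side of the normal one, 2 higher and 5 lower. The proliferating cells were of different kinds, since a cluster that also expressed the intercalated cell genes Atp6v1g3 and Atp6v0d2 held 80 cells of DM1, 1 of DM2 and 0 of NM, while another held 27, 122 and 4. At Leiden resolution 0.5 the injured share was 1.95% in DM2 and 0.885% in NM, and the proliferating share of DM1 was 0.602%. With cells under 25% mitochondrial counts no injured tubule class was named, and the proliferating class held 0 of 392 cells of DM2. There the thick ascending limb made up 0.97% of DM1, 1.53% of DM2 and 1.74% of NM and the distal convoluted tubule 2.98%, 0.510% and 2.65%. Of the 5 lower classes, only dendritic cells and fibroblasts kept both diabetic intervals below the normal one. At resolution 2 fibroblasts made up 2.27%, 3.42% and 3.54%.

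**Figure D1:**
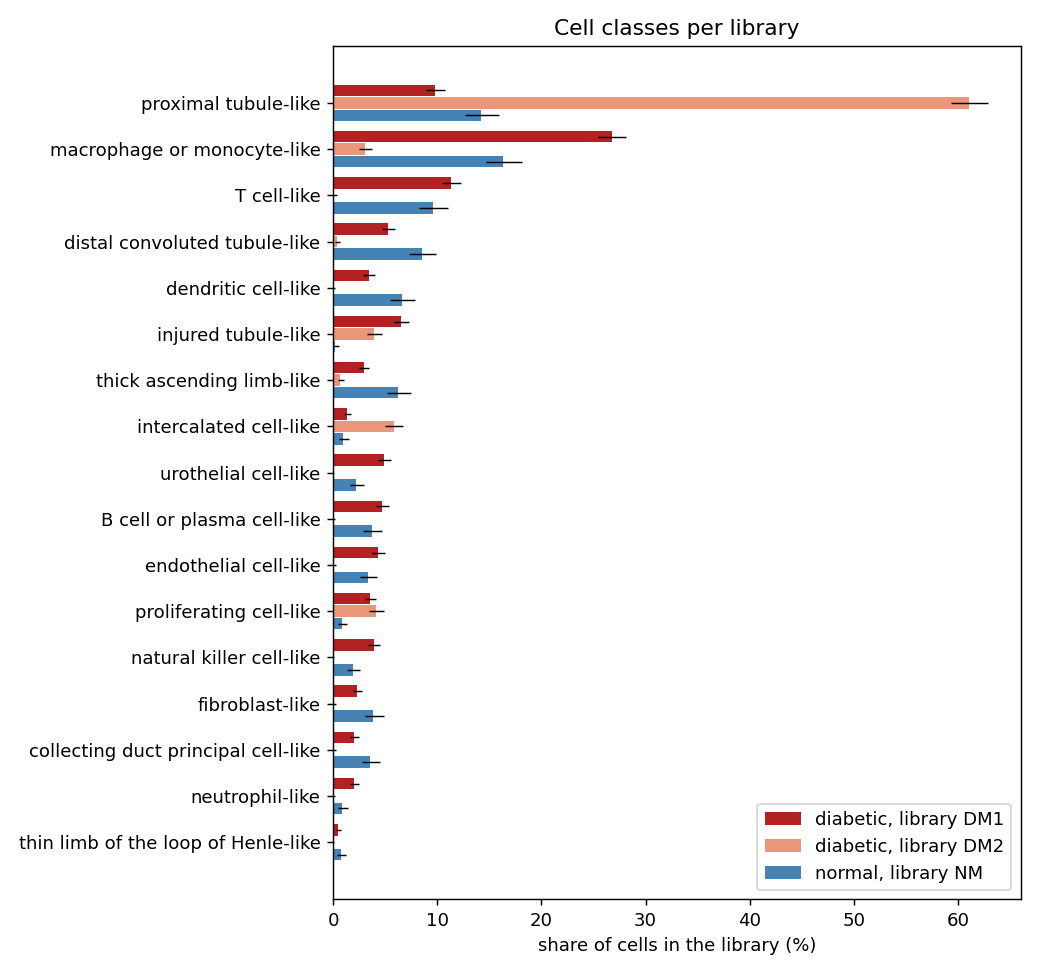
Share of each library's cells (percent) in each named cell class, for the diabetic libraries DM1 and DM2 and the normal library NM, with exact 95% intervals as bars. Injured tubule and proliferating cells lie higher in both diabetic libraries, and the proximal tubule takes 61.1% of DM2.

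Transcripts of the proximal tubule were present in every class, at a level that differed between libraries. The 15 proximal tubule markers, among them the phosphate transporter Slc34a1 and the androgen-regulated Kap, took 2.65% of proximal tubule counts in DM1, 2.44% in DM2 and 5.79% in NM. In macrophages or monocytes their share was 6.22% of the proximal tubule level in DM1 and 6.24% in NM but 42.0% in DM2. In thick ascending limb cells it was 4.86% in DM1, 4.70% in NM and 21.0% in DM2, and in intercalated cells 4.20% in DM1 and 54.4% in DM2.

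**Figure D2:**
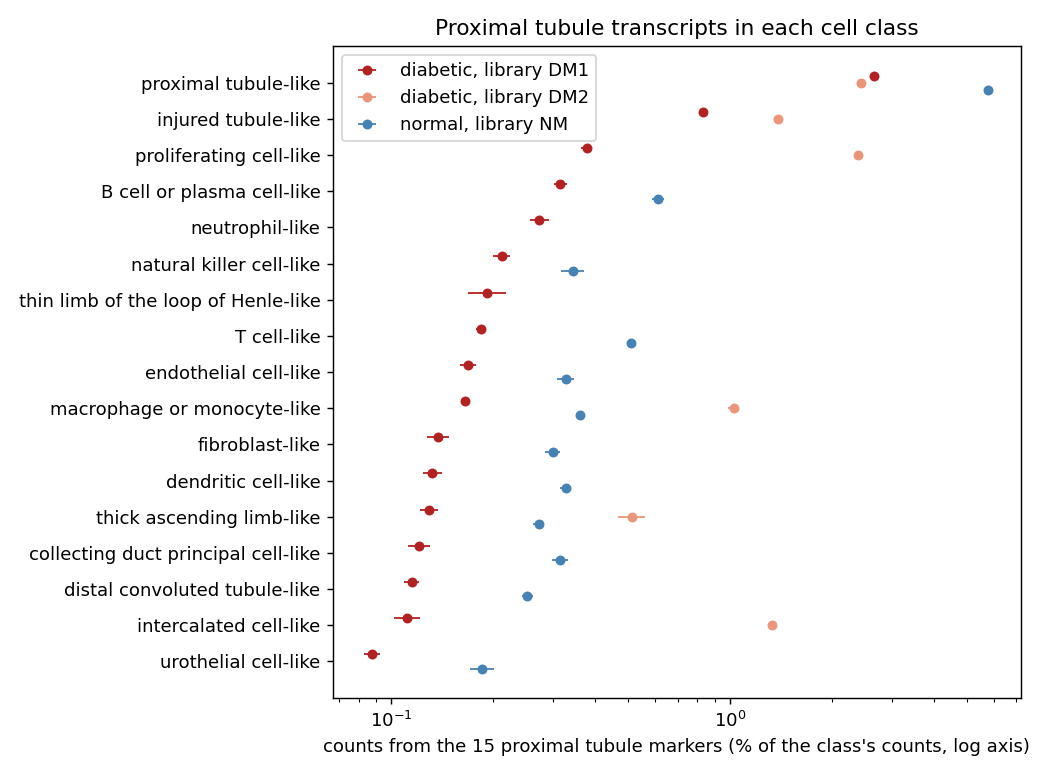
Share of counts taken by the 15 proximal tubule markers (percent, log axis) in each cell class and library, with exact 95% intervals as bars. The shares of DM2 lie above those of DM1 and NM in macrophages or monocytes and in the thick ascending limb.

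The main comparison asked how proximal tubule cells, which reabsorb filtered glucose and make glucose themselves, differed between diabetic and normal kidneys. Several genes of the p53 stress response and of the interferon response rose in both diabetic mice, while Pck1, the key enzyme of glucose production, and several cytochrome P450 genes fell. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 309 CPM in DM1 and 265 CPM in DM2 against 0.907 CPM (2 counts) in NM. These were ratios of 341 (94.0 to 2815) and 292 (80.8 to 2414), and the fitted log2 fold change was 8.13 (SE 0.42, adjusted p = 0.000455). Pck1 was at 520 and 459 CPM against 2119 CPM, a log2 fold change of -2.24 (SE 0.18, adjusted p = 0.00165).

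The other large rises fell mainly into the same groups. Phlda3, a p53 target that restrains Akt, was at 60.1 and 44.5 CPM with 1 count in NM, ratios of 132 (23.5 to 5256) and 98.1 (17.5 to 3888). Ephx1, a microsomal epoxide hydrolase, was at 81.4 and 79.2 CPM with 2 counts in NM, ratios of 89.7 (24.6 to 744) and 87.3 (24.0 to 723). Serpine2, a secreted protease inhibitor, was at 53.8 and 30.5 CPM with 2 counts in NM, ratios of 59.3 (16.2 to 493) and 33.6 (9.18 to 279). Among interferon-induced genes, the antiviral tether Bst2 was 33.0-fold and 30.6-fold higher, the GTPase Iigp1 26.9-fold and 26.1-fold higher, and the transcription factor Irf7, with 3 counts in NM, had ratios of 25.9 (8.66 to 127) and 29.8 (10.1 to 146). The carboxylesterase Ces2e was 26.4-fold higher in DM1 and 12.2-fold higher in DM2. Adjusted p values of these genes ran from 0.000917 for Ephx1 to 0.0162 for Ces2e. On build mm10, Cdkn1a lies on chromosome 17 from 29090976 to 29100727 and Pck1 on chromosome 2 from 173153048 to 173159273.

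Large falls were also found in cytochrome P450 genes, which metabolise drugs and steroids, and in transporters. Cyp2d9 was at 10.1 and 5.73 CPM against 162 CPM, Cyp2a4 at 29.8 and 26.4 against 269 CPM, Cyp2d12 at 20.8 and 13.6 against 126 CPM, and Cyp2a5 at 45.3 and 37.4 against 277 CPM. Slc22a8, an organic anion transporter, was at 115 and 102 CPM against 608 CPM (log2 fold change -2.62, adjusted p = 0.00147). Inmt, a methyltransferase, was at 68.8 and 93.8 CPM against 507 CPM, and the noncoding RNA Snhg11 at 62.6 and 31.4 CPM against 277 CPM. A cluster led by Cyp2a4, Cyp2d9 and Cyp2a5 held 66 cells, all of NM, and without it, which leaves out the normal cells highest in these genes, their log2 fold changes were -1.53, -2.68 and -1.47. Within the S1-like cluster alone, Cyp2a4 and Cyp2a5 were not called.

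**Figure D3:**
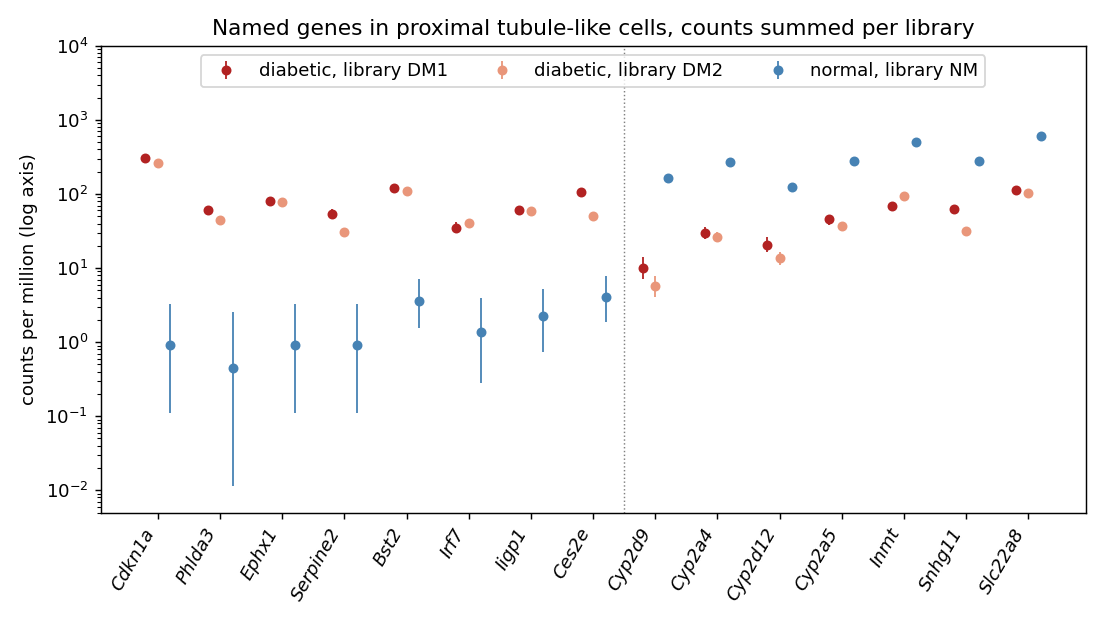
Level of 15 genes taken by the rule in proximal tubule cells (CPM, log axis) per library, rises left and falls right of the dotted line, with exact 95% Poisson intervals as bars. Cdkn1a is at 309 and 265 CPM in the diabetic libraries against 0.907 CPM in NM, and Cyp2d9 at 10.1 and 5.73 against 162 CPM.

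Interferon response genes showed the strongest shared rise among the fixed lists. Camera p values at the preset correlation, here and below, compare genes with genes and carry no error between mice. Of 21 measured members, 11 rose and 0 fell over all genes tested, 17 and 0 adjusted over the list alone, with a median log2 fold change of 3.10, or 2.74 with genes absent in NM at their bound (camera adjusted p = 1.41e-12 with the preset correlation and 0.79 with an estimated correlation). Antigen presentation genes moved with them, with 7 of 14 higher, 12 adjusted over the list alone, and a median of 1.83, or 1.67 at the bound (adjusted p = 3.22e-08, and 0.79 with an estimated correlation). B2m, the light chain of class I molecules, was 3.69-fold and 4.05-fold higher, H2-K1, a class I heavy chain, 4.57-fold and 4.35-fold, and the immunoproteasome subunit Psmb8 5.28-fold and 6.40-fold.

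In the list of p53, apoptosis and senescence genes, 5 of 16 members rose and 0 fell, 9 and 0 adjusted over the list alone, with a median of 0.91 and 14 members higher in both diabetic libraries (camera adjusted p = 1.15e-05, and 0.79 with an estimated correlation). Ccng1, a p53-induced cyclin, was at 447 and 379 CPM against 31.8 CPM. Of 18 injury and repair genes 3 rose, 6 adjusted over the list alone, and 0 fell (adjusted p = 1.4e-05, and 0.79 with an estimated correlation). Spp1 was 7.35-fold and 5.91-fold higher (log2 fold change 2.60, adjusted p = 0.00258). Havcr1 had 42 and 163 counts in the diabetic libraries and 0 in NM, at least 8.43-fold and 18.1-fold higher against the floor of 3 counts in NM (adjusted p = 0.024), and its call ended in 7 of 16 other settings, among them DESeq2 and limma-voom. The injury list's median was 2.54, or 1.99 at the bound, but 0.77 with DM1 alone. Inflammatory genes had 3 of 21 members higher, 5 adjusted over the list alone, with a median of 1.66, or 1.52 at the bound, and 0.63 with DM1 alone (adjusted p = 0.00388, and 0.825 with an estimated correlation). Cxcl10, an interferon-induced chemokine, was 7.23-fold and 13.5-fold higher.

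Metabolic lists went both ways. Of 25 genes of fatty acid oxidation and PPAR targets, the genes that burn fat in these cells, 9 fell and 0 rose, 12 and 2 adjusted over the list alone, with a median of -0.59, or -0.37 with DM1 alone (camera adjusted p = 5.6e-05, and 0.79 with an estimated correlation). Cyp4b1 was at 437 and 660 CPM against 2624 CPM, a log2 fold change of -2.38 that was -0.92 and not called with cells under 25% mitochondrial counts. Of 12 genes of gluconeogenesis 3 fell and 0 rose, 3 and 1 adjusted over the list alone, and the list as a whole did not pass (median -0.30, or 0.0082 with DM1 alone, adjusted p = 0.123). G6pc, which releases free glucose, was at 116 and 93.2 CPM against 248 CPM (adjusted p = 0.0176). Cytochrome P450 and steroid genes had 6 of 15 lower, 9 lower and 2 higher adjusted over the list alone, with a median of -0.68, or -0.40 with DM1 alone (adjusted p = 0.00316, and 0.79 with an estimated correlation). Of 17 lipid and cholesterol synthesis genes, 2 rose, 5 adjusted over the list alone, among them the squalene epoxidase Sqle, 4.24-fold and 3.52-fold higher (list adjusted p = 0.000465, and 0.79 with an estimated correlation).

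Of the transport lists, those of organic ions and of amino acids lay lower. Organic ion transporters had 3 of 14 lower, 9 adjusted over the list alone, with a median of -0.74, or -0.42 with DM1 alone (camera adjusted p = 3.7e-05, and 0.79 with an estimated correlation), but a median of 0.63 with cells under 25% mitochondrial counts. Amino acid transport and metabolism genes had 3 of 22 lower, 9 adjusted over the list alone, with a median of -0.50, or -0.18 with DM1 alone (adjusted p = 0.000998, and 0.79 with an estimated correlation). The androgen-responsive list had 5 of 10 lower, 5 adjusted over the list alone, with a median of -0.93 (adjusted p = 0.00322, and 0.79 with an estimated correlation). Its median was 0.016 without cluster 30, which held only cells of NM and whose removal leaves out the normal cells highest in these genes. The list of tubular sodium, potassium, phosphate and water transport (median 0.037, adjusted p = 0.424) and that of glucose transport (median -0.31, or 0.065 with DM1 alone, adjusted p = 0.0967) did not pass. Slc5a2 (SGLT2) was at 477 and 315 CPM against 317 CPM (adjusted p = 0.729), and Slc2a2 (GLUT2) at 188 and 145 against 136 CPM (adjusted p = 0.736), and neither was called. Slc5a10, a sodium-coupled sugar transporter, fell by 1.79 on the log2 scale (adjusted p = 0.00727), but its call ended in 7 of 16 other settings and it lay at 0.31 in S1-like cells. Txnip, a glucose-induced gene, was not called either (54.9 and 88.3 against 58.5 CPM).

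The remaining 9 lists that passed had few called members. Higher were immediate-early genes, with 2 of 19 called, 10 adjusted over the list alone, and a median of 1.08, complement genes, with 2 of 11 called, 4 higher and 1 lower adjusted over the list alone, and a median of 1.09 (0.46 with DM1 alone), glycolysis genes (0 of 15, median 0.53) and ribosomal proteins (0 of 27, median 0.38). Cell cycle, extracellular matrix and endothelial activation genes had medians of 2.81, 3.04 and 3.09, or 1.16, 1.18 and 1.25 at the bound, but 0.78, 0.85 and 0.32 with DM1 alone, and 0, 0 and 0 called by edgeR over all genes and 0, 1 and 1 adjusted over the list alone. Lower were circadian clock genes, with 2 of 13 called, 7 adjusted over the list alone, and a median of -0.86, and hypoxia genes, with 2 of 13 called, 3 adjusted over the list alone, and a median of -0.51 (-0.14 with DM1 alone). Camera adjusted p values of these lists ran from 0.000473 to 0.0419 and were 0.79 with an estimated correlation, and the glycolysis, ribosomal and hypoxia medians had the opposite sign with cells under 25% mitochondrial counts. C3, the central complement protein, was 8.05-fold and 8.71-fold higher, and Vegfa, an angiogenic factor induced by low oxygen, fell by 1.52 on the log2 scale. The call of C3 ended in 5 and that of Vegfa in 6 of 16 other settings. Vegfa lay at -0.27 with cells under 25% mitochondrial counts. Lists of oxidative stress and NRF2 targets (adjusted p = 0.0855), heat shock proteins (0.186), nuclear-encoded oxidative phosphorylation (0.243), the renin-angiotensin system (0.307) and endoplasmic reticulum stress (0.349) did not pass.

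**Figure D4:**
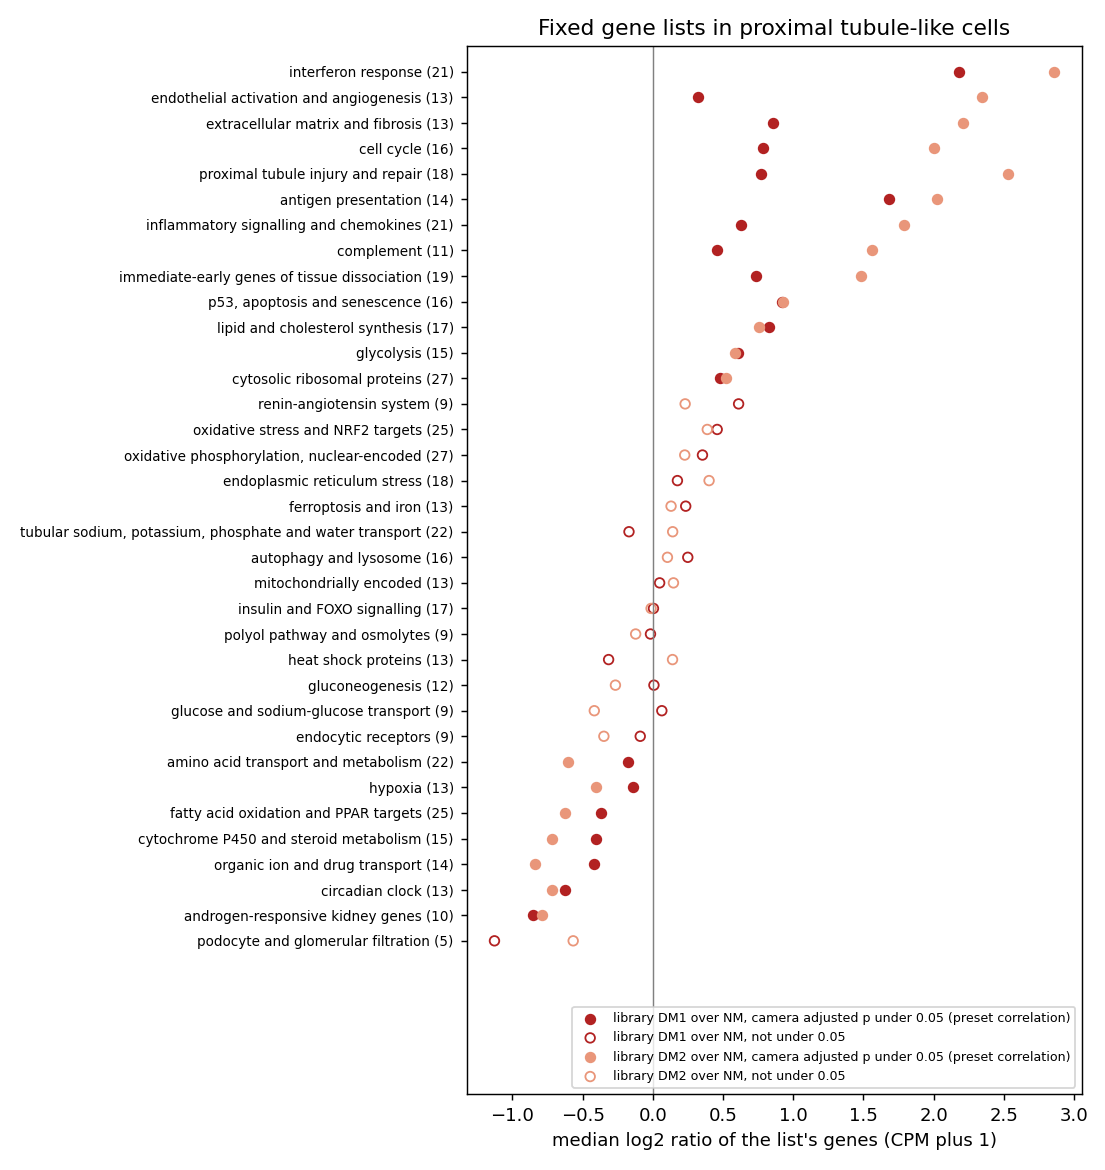
Median log2 ratio of each fixed gene list in proximal tubule cells, for DM1 over NM and DM2 over NM, with filled points where camera passed at an adjusted p under 0.05 with the preset correlation. The interferon response list lies at 2.18 in DM1 and 2.86 in DM2, and the androgen-responsive list at -0.85 and -0.79.

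In the test over all genes of the proximal tubule class, 117 of 10862 genes were higher and 168 lower in the diabetic libraries, with 2081 at an unadjusted p under 0.05. Each of the 285 had the same direction in DM1 alone and in DM2 alone. Both diabetic libraries were set against the same NM, and the test took its error from the difference between them. A shared direction was therefore largely fixed by the calling and is no added support. Of the 35 lists tested in this class 20 passed camera with the preset correlation, and 0 passed with an estimated correlation or by fry, where the smallest adjusted p was 0.252. The preset p values carry no error between mice. The other tests rest on 1 residual degree of freedom and could hardly pass, so neither decides on a list. In both diabetic libraries 1132 of 10528 genes lay at least 2-fold from NM on the same side (915 higher and 217 lower), against 144 when DM1 and 629 when DM2 was the library set apart, and 894 with DM1 alone and 1707 with DM2 alone. The class had a different make-up in each library: cluster 8, rich in mitochondrial transcripts, held 20.0% of its cells in DM1, 64.7% in DM2 and 2.72% in NM, and S3-like cells 30.2%, 15.4% and 54.1%. S3-like cells alone gave 16 higher and 37 lower genes and S1-like cells alone 485 and 520, and Cdkn1a and Pck1 were called in both. The prior degrees of freedom of the variance were 5.91 in the first fit and infinite in the second, so these counts do not measure the effect of make-up.

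The next comparison asked whether other tubule cells showed the same changes, and was possible in the thick ascending limb, which had 131 cells in DM1, 21 in DM2 and 113 in NM. Cdkn1a rose there too. The injury genes Lcn2 and Clu rose in this class, and Egf, the epidermal growth factor precursor made in this segment, fell. In proximal tubule cells without cluster 30, Lcn2 had 2 counts in DM1, 75 in DM2 and 0 in NM, so no shared rise of Lcn2 was shown there. Cdkn1a was at 239 and 392 CPM with 1 count in NM, ratios of 222 (39.4 to 8819) and 364 (61.5 to 14780). Its log2 fold change was 7.85 (SE 1.14, adjusted p = 5.33e-08). The prior degrees of freedom of the variance were infinite in this fit, against 6.67 in the proximal tubule class. Each gene thus took a variance shared over genes, so p values of the thick ascending limb cannot be compared with those of the proximal tubule. Lcn2, which encodes the injury marker lipocalin 2, was 24.8-fold and 110-fold higher (adjusted p = 1.03e-06), and Clu (clusterin) 3.12-fold and 36.6-fold higher (adjusted p = 0.000601), a call that ended with DESeq2, with limma-voom and with no low-count filter. Egf was at 1657 and 487 CPM against 7179 CPM, a log2 fold change of -2.74 (SE 0.61, adjusted p = 0.00576), a call that ended with DESeq2, with no low-count filter and with mitochondrial and haemoglobin genes left out.

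Of 7553 genes tested there, 12 were higher and 2 lower, with 165 at an unadjusted p under 0.05. Il1f6, an interleukin 1 family cytokine, had 5 and 35 counts against 0, and Slitrk4, a membrane protein gene, 1 and 16 counts against 0. Both were called, but not with DESeq2 or limma-voom. Against the floor of 3 counts in NM, Il1f6 was at least 1.91-fold higher in DM1 and at least 115-fold higher in DM2. Umod, the most abundant product of this segment, was at 7919 and 1642 CPM against 16056 CPM and was not called (adjusted p = 0.572). The lower Nsg2 and Adamtsl2 are values only, with 3 and 0 counts in the diabetic libraries against 33 and 27 in NM. In the p53 list 3 of 13 members rose, 4 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 2.72e-07, and 0.79 with an estimated correlation). The interferon list had 0 of 11 called by edgeR over all genes, 2 adjusted over the list alone, and a median of 1.11 (adjusted p = 4.84e-05, and 0.79 with an estimated correlation). Of 9 injury and repair genes 2 rose, 3 adjusted over the list alone, with a median of 1.21, or 0.33 with DM1 alone (adjusted p = 1.15e-05, and 0.79 with an estimated correlation). Heat shock genes lay lower, with a median of -0.49 (adjusted p = 0.0138, and 0.79 with an estimated correlation), and immediate-early genes, at -0.51, did not pass (adjusted p = 0.137). DM2 contributed few cells and much proximal tubule RNA to this class, and when it was the library set apart 75 genes were higher and 111 lower.

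In macrophages or monocytes, the phagocytes of the kidney, the comparison asked whether immune cells changed as well, and no gene passed the test. Cell cycle genes lay higher and heat shock genes, which encode protein-folding chaperones, lay lower in both diabetic libraries. The 18 cell cycle genes had a median log2 fold change of 2.08, or 1.95 at the bound, with 17 members higher in both libraries (camera adjusted p = 2.31e-16, and 0.79 with an estimated correlation). The preset camera p compares genes with genes and carries no error between mice. Only 5 of the 18 cell cycle genes had at least 30 counts summed over DM2 and NM, so most values of DM2 rest on few counts. Stmn1, which regulates microtubules in dividing cells, was at 82.5 and 152 CPM against 22.7 CPM. The 13 heat shock genes had a median of -2.02, with 12 lower in both libraries (adjusted p = 2.06e-15, and 0.79 with an estimated correlation), and Hspa1b was at 679 and 223 CPM against 2673 CPM and Dnajb1 at 148 and 74.2 against 850 CPM. Adjusted over the list alone, 1 cell cycle gene and 0 heat shock genes passed in edgeR. Arg1, the arginase of alternatively activated macrophages, had 38 and 47 counts against 0, and Lyve1, a marker of resident macrophages, 58 and 9 against 0, at least 4.53-fold and 87.6-fold, and 6.91-fold and 16.8-fold, above the floor of 3 counts in NM. Ces2e had 52 and 8 counts against 0.

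Of 9971 genes tested in this class by edgeR, 0 were higher and 0 lower, with 172 at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 110 and 107 at an unadjusted p under 0.05, and edgeR without a low-count filter called Arg1 alone. The class differed in kind between libraries, since 86 of the 91 cells of DM2 lay in a cluster marked by Retnla, Fcna and Pf4 that held 36 of 1200 cells of DM1 and 8 of 295 of NM. A test of whether the diabetic change differed between proximal tubule cells and macrophages or monocytes called 0 of 11782 genes by edgeR, with 129 at an unadjusted p under 0.05, so no gene was shown to differ in its change between them.

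Over all cells of a library, edgeR called 0 of 14119 genes, with 222 at an unadjusted p under 0.05, limma-voom 0, with 180, and DESeq2 9 higher and 1 lower. Cdkn1a was at 317 CPM in DM1 and 280 CPM in DM2 against 80.5 CPM in NM, and Havcr1 had 626 and 328 counts against 0. Sums over all cells also move with the make-up of each library, which was not separated here from change within cells. In both diabetic libraries 570 genes lay at least 2-fold from NM, against 602 when DM1 and 2871 when DM2 was set apart, and 1268 with DM1 alone and 3224 with DM2 alone.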

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

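The tests of free RNA and of doublets in DM2 were chosen only after the result was seen. Several gene lists moved one way in both diabetic libraries in proximal tubule cells and the other way in both in another class, and these differences between classes were not tested. Proximal tubule minus thick ascending limb, the difference in median fitted log2 fold change was 1.58 for immediate-early genes of tissue dissociation, 0.12 for mitochondrially encoded genes, -0.45 for hypoxia genes, -1.65 for organic ion and drug transport, -1.14 for endocytic receptors and -1.12 for amino acid transport and metabolism. With DM1 alone these were 1.45, 0.079, -0.24, -0.53, -0.39 and -0.42, so the last 3 rest largely on DM2, whose thick ascending limb cells carried proximal tubule markers at 21.0% of the proximal tubule level. Proximal tubule minus macrophages or monocytes, it was 1.89 for immediate-early genes, 1.19 for complement, -0.52 for the polyol pathway and osmolytes and 1.01 for cytosolic ribosomal proteins, and with DM1 alone 0.97, 0.59, -0.27 and 0.50. The ribosomal list had a median of 0.38 in proximal tubule cells but -0.24 with clusters 6 and 29 added and -0.59 with cells under 25% mitochondrial counts.

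A signal also appeared in clusters left without a class name, which entered only the sums over all cells and, for those with little Malat1, a proximal tubule setting with clusters 6 and 29 added. A cluster with the urothelial genes Upk3a and Upk1a, which coat the urinary surface, held 17.0% of the cells of DM2, with 14 cells of DM1 and 0 of NM. A cluster with the fat cell genes Cfd, Car3, Fabp4 and Retn held 3.29% of DM2, with 5 cells of DM1 and 0 of NM. A cluster with the glutathione transferases Gsta1 and Gsta2 and little Malat1 held 3.68% of DM1 and 0.830% of NM but 0.101% of DM2. Another cluster with Gsta2 and little Malat1 held 15.2% of NM against 0.134% of DM1 and 0.0335% of DM2.

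Proximal tubule transcripts filled every cell class of DM2 that held at least 20 cells. Across the 15 proximal tubule markers, the log2 level in intercalated cells of DM2 followed that in its proximal tubule cells with a Pearson r of 0.989 across genes, which are not independent replicates, and the median level was 60.5% of the proximal tubule level against 3.46% in DM1. A single shared source such as free RNA from broken proximal tubule cells is a candidate explanation. Doublets with whole proximal tubule cells were argued against, since intercalated cells of DM2 held a median of 1.03 (0.983 to 1.08) times the UMIs of its proximal tubule cells, where pairs of cells would hold more. Diabetes as the reason was not tested, since DM1 did not share the pattern.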

How the results depend on the processing

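The settings that changed the clusters in the proximal tubule class, and those for list medians other than the estimated correlation and the left-out libraries, were chosen only after the data were seen. Where no cause is named, the cause was not tested. In the proximal tubule class the main test gave 117 higher and 168 lower genes. It gave 699 and 578 with no low-count filter, 75 and 105 with DESeq2, which tested fewer genes, and 44 higher with limma-voom. It gave 725 and 833 with cells under 25% mitochondrial counts, 69 and 93 at Leiden resolution 0.5, 245 and 332 at resolution 2, and 15 and 27 with cells thinned to 2000 UMIs, which left fewer counts. It gave 72 lower with clusters 6 and 29 added, 10 and 26 with the injured tubule cluster added, 411 and 541 without cluster 8, 485 and 520 in cluster 14 alone, 16 and 37 in clusters 18 and 30, 68 and 80 without cluster 30 and 30 and 41 in cluster 18 alone. Of the 285 genes called, all that were tested kept their direction with DESeq2 size factors, no low-count filter, DESeq2, limma-voom, and mitochondrial and haemoglobin genes left out. They also kept it with the injured cluster added, without cluster 8, at both other Leiden resolutions and with thinned cells. All settings reused the same libraries, so a kept direction is no independent support. The opposite direction was found for 34 of 281 with cells under 25% mitochondrial counts. It was found for 11 of 276 in cluster 14, 5 of 271 in cluster 18, 2 of 285 without cluster 30 and 1 each in clusters 18 and 30 and with clusters 6 and 29 added. Under the 25% limit the normal class went from 257 to 334 cells and unnamed NM cells from 295 to 14. Median mitochondrial shares of NM cells were 29.3%, 41.0% and 33.3% in clusters 14, 18 and 30 but 9.83% in unnamed cluster 29. The normal class there thus held largely other cells, so sign changes and lost calls in that setting do not measure the mitochondrial limit alone.

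Of the proximal tubule genes named as called, Pck1 and Ccng1 were called in all 16 other settings with a test, and Cdkn1a and Ephx1 in all but limma-voom, which also ended the calls of Phlda3, Serpine2, Irf7, Iigp1, Ces2e, Cxcl10, C3 and Havcr1. The falls of Cyp2a5, Slc22a8, Cyp4b1, Slc5a10, Vegfa, G6pc and Kap were not called with cells under 25% mitochondrial counts, and those of Cyp4b1, Slc5a10, Vegfa, G6pc and Kap also not with clusters 6 and 29 added. Calls ended in 7 settings for Havcr1 and Slc5a10, 6 for Vegfa, 5 for Serpine2, Ces2e, Cxcl10, C3 and G6pc, and 4 for Irf7, Iigp1, Sqle, Psmb8 and Kap. Slc5a10 was at 0.31 in cluster 14. The thick ascending limb gave 7 higher and 1 lower with no low-count filter, 2 and 0 with DESeq2, 4 and 5 with limma-voom, and 0 lower with mitochondrial and haemoglobin genes left out, which removed a haemoglobin gene. Macrophages or monocytes gave 1 higher with no low-count filter. Over all cells DESeq2 gave 9 higher and 1 lower. Genes at least 2-fold from NM in both diabetic libraries numbered 511 in the proximal tubule class and 339 over all cells at a count minimum of 100, which leaves fewer genes, and with 1 diabetic library left out 894 to 1707 and 1268 to 3224. Classes with both diabetic intervals on the same side of the normal one went from 7 to 3 with cells under 25% mitochondrial counts. They went to 12 to 17 with a diabetic library left out, since the interval of 1 library then decides.

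With an estimated correlation 0 lists passed in any class, against 49 pairs of list and class, and 0 in the proximal tubule class, against 20. That setting rests on 1 residual degree of freedom, so a list could hardly pass. Of the proximal tubule lists 13 passed in cluster 14 alone and 12 in cluster 18 alone. Some medians changed sign in that class. With cells under 25% mitochondrial counts, glycolysis was at -0.45, hypoxia at 0.0013, organic ion transport at 0.63 and ribosomal proteins at -0.59. Ribosomal proteins were at -0.24 with clusters 6 and 29 added and androgen-responsive genes at 0.016 without cluster 30, which removes the normal cells highest in them. With DM1 or DM2 left out, medians in macrophages or monocytes ran from -1.58 to 0.19 for antigen presentation, -0.18 to 2.31 for organic ion transport, -0.20 to 2.44 for endocytic receptors and -0.18 to 1.68 for amino acid transport, and that of cytochrome P450 genes in the thick ascending limb from -0.10 to 1.86, with the other sign each time without DM2.

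Among genes not called in the proximal tubule class, log2 fold changes turned as follows. Slc5a2 was at -0.00887 with the injured cluster added, -0.22 in cluster 14, -0.30 without cluster 30 and -0.34 in cluster 18. Slc5a1 was at 0.51 with clusters 6 and 29 added, 6.08 in cluster 14 (a fit to 3 and 16 counts against 0 in NM, which gives no size), 0.049 in clusters 18 and 30, 1.38 without cluster 30, 1.21 in cluster 18 and 1.20 under 25% mitochondrial counts. Slc2a2 was at -0.035 in clusters 18 and 30 and -0.23 in cluster 18. Txnip was at -0.016 without cluster 8, -0.11 in cluster 14 and -0.00529 at Leiden resolution 2. Angptl4 was at 0.57 with clusters 6 and 29 added, 0.21 in cluster 14, 0.0825 in clusters 18 and 30, 0.21 without cluster 30, 0.32 in cluster 18 and 0.94 under 25% mitochondrial counts. Gpx3 was at 0.22 with clusters 6 and 29 added, 0.093 in clusters 18 and 30, 0.31 under 25% mitochondrial counts and 0.0017 with thinned cells. No mitochondrial limit and keeping the Scrublet calls changed no cell, so they test nothing. No paired analysis was possible because the mice were not paired, and a library left out leaves values with no test.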

Other observations

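The tests of dissociation stress, entry through Slc2a2 and segment mix were chosen only after the result was seen, while those of free RNA and of depth per cell were written before, the latter without its comparison of the same genes before and after thinning. Most cell classes had too few cells in DM2 or NM to be tested, and in most of these DM1 alone was set against NM, 1 library against 1, as values with no test. Genes of the p53 list lay higher in DM1 in most of these classes, with a median log2 ratio of 1.29 in fibroblasts (11 of 11 genes higher), 1.21 in the distal convoluted tubule (12 of 12), 0.78 in principal cells and 0.74 in B cells, but 0.21 in urothelial cells, 0.19 in endothelial cells, 0.061 in natural killer cells and -0.13 in dendritic cells, which present antigen. In intercalated cells, of which NM had 18, Cdkn1a was at 461 CPM in DM1 and 248 CPM in DM2 against 7.22 CPM (1 count) in NM. In DM1 it was at 147 against 16.8 CPM in the distal convoluted tubule and at 157 against 9.99 CPM in B cells. Interferon genes lay higher by 1.99 in the distal convoluted tubule, 1.05 in fibroblasts, 0.98 in natural killer cells and 0.77 in endothelial cells, and lower in urothelial cells at -0.86.

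Heat shock genes, which encode chaperones, lay lower in DM1 than in NM in all 12 classes for which DM1 gave a value, with medians of -1.61 in macrophages or monocytes, -1.52 in dendritic cells, -1.20 in natural killer cells, -0.94 in T cells and -0.06 in fibroblasts. In T cells 12 of 13 cell cycle genes lay higher in DM1, with a median of 1.53. Egf, which fell in the thick ascending limb, was at 1157 CPM in the distal convoluted tubule of DM1 against 2351 CPM in NM.

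The rise of p53 target genes in proximal tubule cells was weighed against 2 technical explanations. For dissociation stress a rise of 2 stress lists was needed. The heat shock list did not rise, with a median log2 ratio of -0.147 (-0.349 to 0.00557) in these cells, while immediate-early genes did, at 1.13 (0.702 to 1.26). Heat shock genes lay lower in DM1 than in NM in every class for which DM1 gave a value. A ratio to NM therefore cannot exclude stress in the diabetic cells, and dissociation stress stays open. Free RNA was argued against in DM1, where the 5 called genes of the list took 3.65 (3.34 to 4.00) times the share of counts in proximal tubule cells that they took in T cells, and stays open in DM2, which had 4 T cells. A possible explanation from the treatment is that streptozotocin, which damages DNA, entered cells through Slc2a2 (GLUT2), but the highest p53 median among classes with little Slc2a2, that of fibroblasts, lay 0.268 (-1.60 to 1.29) above that of the proximal tubule class, with 2 of 9 such classes at or above it, which leaves this open. Diabetes itself, streptozotocin in cells without Slc2a2 and any other feature of the single normal library stay open and untested.

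The lower level of androgen-responsive genes in diabetic proximal tubule cells was weighed against the mix of tubule segments and the depth per cell. Within the S1-like cluster 14 the list's median log2 ratio was -0.183 (-1.03 to 0.332), and within the S3-like clusters 18 and 30 it was -0.359 (-1.23 to 0.167), against -0.819 in the whole class. Cluster 30 was kept in, since it held only cells of NM and was led by genes of this kind. Without it the list's median fitted log2 fold change in the whole class was 0.016, so the lower level of the list rests on whether these cells are counted. Single members still fell within segments. Kap was at 33445 CPM in DM1 and 31229 CPM in DM2 against 61544 CPM in NM within clusters 18 and 30 (log2 fold change -1.13, adjusted p = 0.0112), and was called in cluster 18 alone as well (-0.70, adjusted p = 0.0158). Within cluster 14 it was at 1457 and 5400 CPM against 3867 CPM and not called. Cyp4b1 and Cyp4a12a were called lower within cluster 14 and within clusters 18 and 30. With 10 genes the intervals of both medians were too wide to decide for the list, so a change in the segments captured and in androgen response cannot be told apart. With every cell thinned to 2000 UMIs the median was -0.836, so it stayed below -0.3. The same genes shifted by a median of 0.108 (0.0364 to 0.215), where 0.519 was needed to reach -0.3. Thinning keeps the expected share of each gene within a cell, so beyond sampling noise it changes only the weight of each cell in the sum. The test therefore cannot decide on depth per cell, which stays open. Thinning moved 16 of 477 well-counted genes by more than 5 Poisson SD in a library.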
